A study of Drosophila melanogaster with 2 samples.

How the data were processed

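The series holds 2 samples of 1 group: Kc167 cells, a line derived from Drosophila melanogaster embryos, assayed by Hi-C, in which cross-linked chromatin is cut, its ends are ligated and the ligation products are sequenced to count contacts between genomic positions. Per the labels' protocols, cells grown at 25 °C were fixed with 1% paraformaldehyde. Proteins were biotinylated, the DNA was cut with DpnII, and ligation took place with the chromatin bound to streptavidin beads (tethered Hi-C). The purified DNA was sheared to about 500 bp before library preparation. The labels call one sample primary and the other a replicate, and the series' design text calls them independent biological replicates.

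The deposited values are 2 lists for the whole series, made from the 2 samples combined, as the file names state. Per the submitters' processing notes, the reads were processed with BWA and Juicer on the dm3 (BDGP5) build. Versions, the callers of domains and loops and their settings are not given in the sources used here. The first list holds contact domains (TADs, stretches that contact themselves more than their surroundings), each with a start, an end and 5 scores. These are the authors' own score values per domain, per the file headers, with no stated scale. The one named simply score is called the corner score here, and the other 4 were not used. The second list holds loops, pairs of anchors with enriched contact, as positions only, with no score, read count or p-value. How the loops were chosen is not given in the sources used here. No contact counts per sample were analysed here, so the sequencing depth behind each domain and loop is unknown, and no value has a spread between the 2 samples. All intervals and p-values below describe domains, anchors or loops within 1 pooled map, and cover no biological error. Neighbouring features are not independent, so p-values from permuted domain labels and from random draws of loops, which treat them as independent, can be too small. Both lists come from the same map, so a feature of the map could enter both.

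All 2126 domain starts and ends lie on a 500 bp grid and no domain overlaps another. Domain starts are given here as the listed start plus 1, and loop anchors as listed. Each arm was taken to extend from 0 to the largest position in the lists. Anchors that overlapped or touched were merged into distinct anchors, represented by their midpoints. Loop spans are distances between anchor midpoints. Medians have percentile bootstrap intervals (95%, 10000 draws over features). Shares have exact Clopper-Pearson intervals and counts per arm exact Poisson intervals (95%), which cover counting error only.

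Lengths were compared between arms by permuting arm labels over domains 100000 times with the Kruskal-Wallis statistic, and between X and the arms 2L, 2R, 3L and 3R with the difference of medians. Loop numbers per arm were compared with arm extent by 100000 multinomial draws. The positions of loops and anchors relative to domains were compared with 10000 circular shifts, in which all features of an arm moved together by 1 random offset and wrapped at the arm end. For the Kruskal-Wallis and chi-square statistics, p counts draws with a value at least as large as observed. The other tests were two-sided. The smallest p that the shifts can give is 0.0002, and the smallest for the permutations is 1e-05. An anchor was near a domain end within 5 kb, and a loop was at a domain corner when its anchors lay within 10 kb of the start and of the end of 1 domain. These rules, the alternatives other than those on loops under 1 Mb, on linked loops counted once and on loop numbers of the large arms, and the regions to be named (the 5 longest and 5 shortest loops, the anchors with most loops, the 5 longest domains and the 5 with the highest corner score) were fixed before the data were examined. The rule allowed 5 anchors, but 7 tied for most loops and all 7 are named. All 7 loops over 1 Mb, the corner loops, the domains with 3 whole loops, the longest stretches between domains and the loops joining 4 anchors on 3R were chosen for naming after their values were seen. So were the contrasts of single arms and the distance classes of anchors.

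The code of the tests was run on simulated data, with fewer shifts and permutations than used on the lists. Of 100 sets of loops shifted at random, the near-end, corner and inside-domain tests called 4, 1 and 3. With 20% of the 120 loops moved to domain corners, they called 20, 20 and 13 of 20 sets. The moved anchors lay exactly on domain ends, and the mean near-end share was 40.9%, above the 30.2% of the list. The 2 shares differ in unit, as the simulated test counted every loop end and the list test counted distinct anchors. Power of the near-end test for a smaller excess was thus not shown. The arm-length test called 3 of 100 sets with permuted lengths, and 20 of 20 sets with the 2R lengths multiplied by 0.8. The sets with nothing planted were drawn by the same shifts or permutations that the tests use. Their low call rates were therefore given in advance and check the code only, not the tests on features that depend on each other.

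Comparisons of 11 fixed gene lists and of sequence motifs with anchors and domain ends had been planned. They were not run, because a genome or annotation of the dm3 build was not used here and the gene table at hand is of Release 6, whose coordinates cannot be set against these lists. Regions are therefore named by dm3 coordinates. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.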

Results

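The combined Hi-C map of 2 Kc167 samples was deposited as 2126 contact domains and 120 loops on the arms 2L, 2R, 3L, 3R, 4 and X of the dm3 build. All loops joined 2 positions of the same arm. With 1 group and pooled lists, the map offers comparisons between arms and between loops and domains, and none between samples.

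The first question was how the genome is divided into domains. The domains covered 95.4 Mb, or 79.5% of the 120 Mb spanned by the lists. They were mostly short, with a median length of 21.5 kb (95% bootstrap interval 20 to 22.5 kb, n = 2126) and quartiles at 12.5 and 44 kb. The shortest were 6 kb long. The few long ones held much of the sequence: 233 domains over 100 kb, 11% of the list, accounted for 48% of all domain length. The longest spanned 740 kb, on 3R from 2980001 to 3720000. The next were 625 kb on 2L (17500001 to 18125000), 600 kb on 3R (11190001 to 11790000), 575 kb on X (21845001 to 22420000) and 540 kb on X (11925001 to 12465000). Among these 5, the 575 kb domain on X held 1 whole loop and the other 4 held no anchor.

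Neighbouring domains were usually close together. The median gap between them was 3.5 kb, and 786 of 2120 gaps (37.1%) were 2 kb or shorter. In 93 places over 50 kb lay between domains, 9.37 Mb in total. The longest such stretches were 529 kb on 3L (23766001 to 24295000), 369 kb on X (21476001 to 21845000) and 253 kb on 2L (22599001 to 22852000).

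Domain length differed between arms. Chromosome 4, the small dot chromosome, had the longest typical domain, with a median of 37 kb (bootstrap interval 33 to 50 kb, n = 21) and none over 88 kb. On 2R the domains were short, with a median of 19 kb (17.5 to 20.5 kb, n = 443), and 7.22% of them exceeded 100 kb. On 2L the median was 25 kb (21 to 27 kb, n = 364), and 13.2% exceeded 100 kb. The arms 3L, 3R and X lay between, at 21, 21.5 and 22.5 kb. The overall difference was larger than that between randomly labelled domains (Kruskal-Wallis H = 20.1, permutation p = 0.00122). In contrasts of each arm with the rest, run after that result, mean ranks differed for 2R (permutation p = 0.00255, Benjamini-Hochberg adjusted over 6 arms 0.0148) and chromosome 4 (p = 0.00495, adjusted 0.0148), while 2L did not pass (p = 0.0255, adjusted 0.0511). These contrasts had first been run over the 5 large arms alone, where 2L did pass (permutation p = 0.0196, adjusted 0.049) along with 2R (adjusted 0.0215), so the call for 2L rests on whether chromosome 4 is included. X exceeded the 4 large autosome arms by 1.5 kb in the median, which was within the spread of permuted labels (permutation p = 0.39). In the upper 25% of domains by corner score the difference between arms was no longer detectable (H = 5.99, permutation p = 0.311, n = 532).

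**Figure D1:**
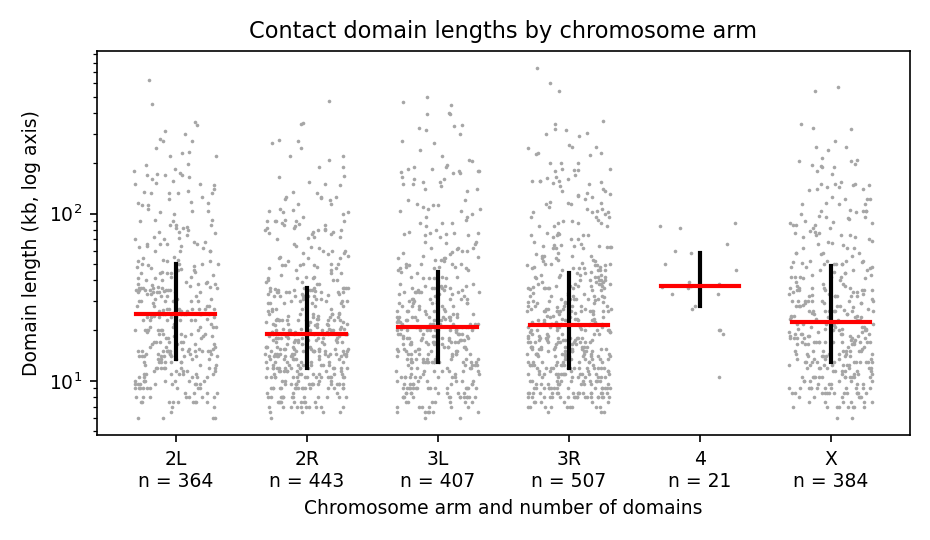
Length of each of the 2126 contact domains (grey points, kb, log axis) by chromosome arm, with the median (red line) and the quartiles (black bar). The median is highest on chromosome 4, at 37 kb over 21 domains, and lowest on 2R, at 19 kb over 443 domains.

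Corner scores, the authors' own measure of each domain, rose with length across domains (Spearman rho = 0.43, permutation p = 1e-05, n = 2126, with domains not being independent replicates). The correlation was weaker among the upper 50% of domains by score (rho = 0.28, n = 1063) and the upper 25% (rho = 0.15, n = 532), subsets that narrow the range of the score itself. The highest scores belonged to domains of very different size: 300 kb on 3R (6720001 to 7020000, score 1.91), 126 kb on 2R (7342001 to 7468000, 1.91), 63 kb on 3R (10153001 to 10216000, 1.91), 156 kb on 3R (308001 to 464000, 1.90) and 17 kb on 3L (630501 to 647500, 1.90). The first and the second of them each held 1 whole loop.

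The second question was where loops occur and how far they reach. The 120 loops had a median span of 53.2 kb (bootstrap interval 46 to 66.8 kb) with quartiles at 32.2 and 97.1 kb, and anchors with a median width of 2 kb. The spans fell into separate ranges: 113 loops reached from 10 to 240 kb, and 7 reached over 1 Mb. The longest loop joined X 900001 to 908001 with X 15954001 to 15960001, 15.1 Mb apart. On 2R the anchor 4680001 to 4690001 had a loop of 6.31 Mb to 10990001 to 11000001 and a second of 6.21 Mb to 10895001 to 10905001, and these distal anchors overlapped those of a shorter loop that joined them to each other. The others over 1 Mb spanned 5.99 Mb on X (13240001 to 13255001 with 19225001 to 19245001), 3.11 Mb on 2L (6354001 to 6362001 with 9462001 to 9470001), 2.67 Mb on 3L (6645001 to 6650001 with 9320001 to 9325001) and 1.32 Mb on 3R (2644001 to 2650001 with 3960001 to 3970001). The shortest were 10 kb on X (13908001 to 13910001 with 13918001 to 13920001), 11 kb on 3L (22817001 to 22818001 with 22828001 to 22829001), 12.5 kb on 2L (14518001 to 14520001 with 14530001 to 14533001), 13 kb on 2L (3094501 to 3096001 with 3107501 to 3109001) and 14.5 kb on X (4305001 to 4306501 with 4319001 to 4321501).

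**Figure D2:**
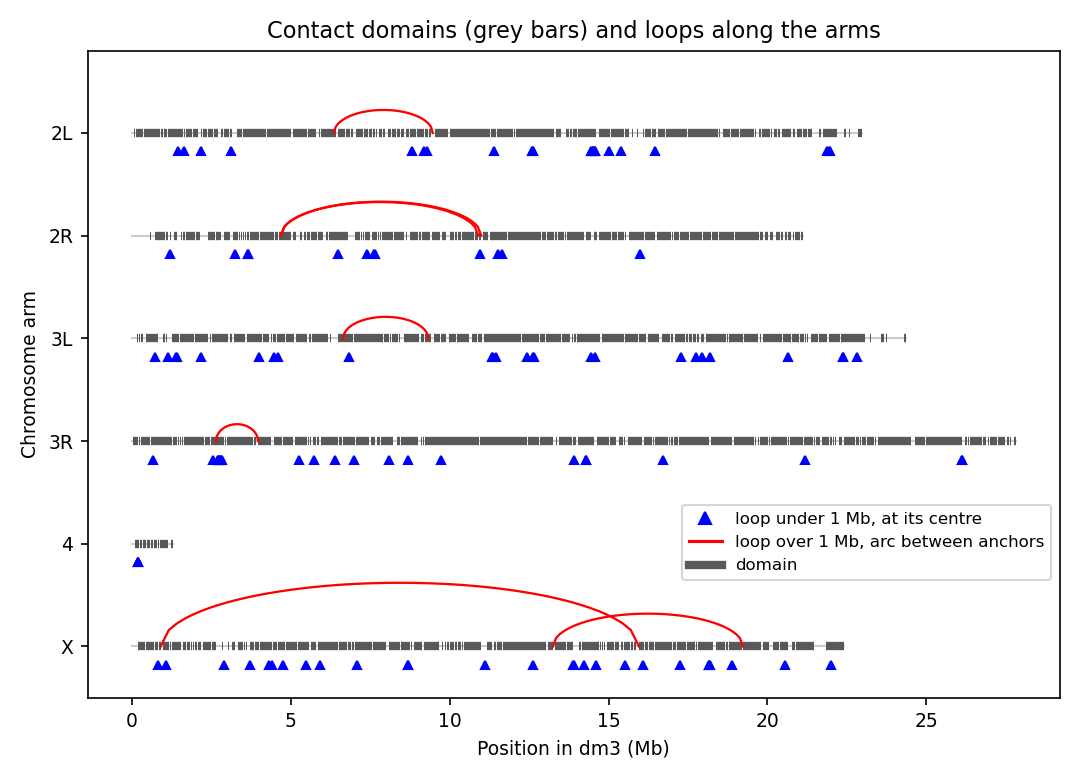
Domains (grey bars), the 113 loops under 1 Mb (blue triangles, at the loop centre) and the 7 loops over 1 Mb (red arcs between their anchors; arc height has no scale) along the 6 arms, by dm3 position in Mb. Loops are found on every arm, and the 2 arcs on 2R share their left anchor.

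Among the large arms loops were most frequent on X, with 29 loops or 12.9 per 10 Mb (exact Poisson interval 8.66 to 18.6), and least frequent on 2R, with 14 loops or 6.62 per 10 Mb (3.62 to 11.1). The arms 2L, 3L and 3R had 10.4, 10.7 and 8.63 loops per 10 Mb, and chromosome 4 had a higher rate than X, 23.4 per 10 Mb, from 3 loops in 1.28 Mb (4.83 to 68.4). The 3 loops on chromosome 4 share 1 anchor, which the interval does not take into account. The loop numbers per arm did not differ from those expected by arm extent by more than random draws (multinomial chi-square 7.32, p = 0.193, n = 120). Expected values set by the number of domains per arm instead gave a chi-square of 11.8 (p = 0.0399, n = 120).

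The loops used 202 distinct anchors, of which 171 took part in 1 loop, 24 in 2 and 7 in 3. Of the 120 loops, 43 belonged to 15 sets linked by shared anchors. The anchors with 3 loops were 14517001 to 14520001 and 14598001 to 14601001 on 2L, 152001 to 154001 on chromosome 4, and 4 on 3R: 2672001 to 2676001, 2718001 to 2721001, 2825001 to 2828001 and 2862001 to 2864001. These 4 anchors on 3R were joined in all 6 possible pairs, over spans of 37 to 190 kb. Of the 6 loops, 2 lay within a domain and 4 crossed from the domain 2650001 to 2734000 into the domain 2738001 to 2890000.

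The third question was how loops lie relative to domains. Most loops stayed inside a single domain: both anchors of 77 of 120 loops lay in the same domain, or 64.2% (exact interval 54.9 to 72.7%), against 30.6% after circular shifts (central 95% from 21.7 to 40%, p = 0.0002, the smallest the shifts can give). This was a 2.1-fold excess, and it was present when any of the 5 large arms was left out (62.8 to 65.1%) and when 1 loop was counted per set of shared anchors (67.4% against 33.4%). The 77 loops lay in 58 domains with a median length of 150 kb over loops, and spanned a median of 34.5% of the domain (quartiles 20.1 and 51.7%). Domains at 2L 12564001 to 12690000, 2L 14365001 to 14595000, 2L 21760001 to 22115000, 3L 11215001 to 11515000 and X 18135501 to 18212500 each held 3 whole loops. Of the other loops, 12 had anchors in 2 different domains, 20 had 1 anchor between domains and 11 had both there. Among the 36 loops under 1 Mb that were not inside a domain, 13 had 1 domain start or end between their anchor midpoints, 11 had 2, 8 had 3 or more, and 4 had none.

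A smaller group of loops joined the start and the end of a domain. At 10 kb tolerance 17 of 120 loops were at a corner, or 14.2% (exact interval 8.47 to 21.7%), against 5.44% after circular shifts (central 95% from 1.67 to 10%, p = 0.0006). Of these 17, 5 also lay inside a domain and are among the 77 above. Within 5 kb the count was 12, or 10% against 1.48% (p = 0.0002, n = 120), the smallest p the shifts can give. On 3L the anchors 2170501 to 2172001 and 2191501 to 2193001 lay at the ends of the domain 2171001 to 2192000, and the anchors 17732001 to 17733501 and 17756501 to 17758001 at those of the domain 17732001 to 17758000. On X the anchors 17199001 to 17200001 and 17316001 to 17317001 lay at the ends of the 114 kb domain 17200001 to 17314000. On 3R the anchors 26103001 to 26109001 and 26132001 to 26135001 lay at the ends of the domain 26103001 to 26134000. At 20 kb tolerance the share was no longer distinguishable from shifts (20.8% against 17.4%, p = 0.371, n = 120), and neither was it with the upper 25% of domains by corner score (3.33% against 1.29%, p = 0.144).

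Whether single anchors were more often near a domain end than by chance depended on how chance was set: 61 of 202 lay within 5 kb, or 30.2%, against 26.2% after circular shifts (central 95% from 19.8 to 32.7%, p = 0.242, n = 202), the comparison fixed for the test. Against anchors placed one by one inside domains the call changed (22.3%, p = 0.0106, n = 202). That placement left out the gaps between domains, where 35 of the 202 observed anchors lay, so it is not a like comparison. Of the 167 anchors in domains, 21% lay within 5 kb of an end, no more than that 22.3%. The call also changed when these 167 were moved inside their own domain, a comparison added after the data were seen (21% against 13.3%, p = 0.0026, n = 167). Under circular shifts, narrower and wider distances went opposite ways. Within 2 kb there were more anchors than after shifts (43, or 21.3% against 13%, p = 0.0026, n = 202), and within 20 kb there were fewer (89, or 44.1% against 57.3%, p = 0.0018). Split into distance classes after those results, anchors were fewer at 5 to 10 kb (5.94% against 14.6%, Benjamini-Hochberg adjusted over 6 classes p = 0.0012, n = 202) and at 10 to 20 kb (7.92% against 16.5%, adjusted p = 0.0018), and more at 20 to 50 kb (28.2% against 21.4%, adjusted p = 0.039). Anchors lay inside domains in 167 of 202 cases, or 82.7%, against 80.1% after shifts (p = 0.468, n = 202).

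**Figure D3:**
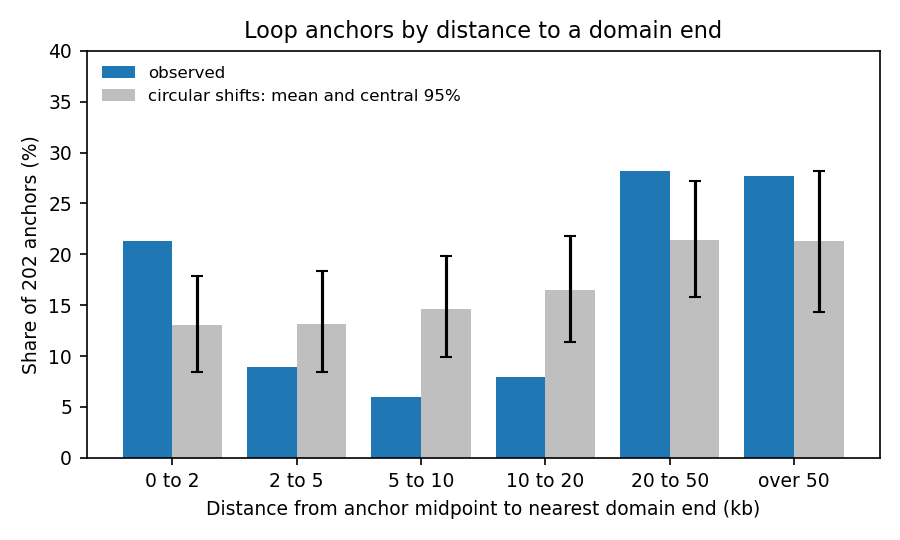
Share of the 202 distinct loop anchors (%) by distance in kb from the anchor midpoint to the nearest domain end, as observed (blue) and after 10000 circular shifts (grey, mean; error bars, central 95%). The observed share exceeds the error bar at 0 to 2 kb (21.3%) and at 20 to 50 kb (28.2%) and lies under it at 5 to 10 and 10 to 20 kb.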

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

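With 1 pooled list of each kind, no sample could be left out. No paired analysis was possible because the lists hold no values per sample. No domain overlaps another, so the outermost and the innermost domains are the whole list and gave the same values by construction. No domain reaches 1 Mb, so leaving out the longer loops could not change the calls for loops inside domains or at corners. The numbers of alternatives below include these. The share of loops inside a domain kept its direction and stayed past the threshold in all 13 alternatives, between 46.7 and 68.1%. The share at domain corners did so in 13 of 15, and was past the threshold neither with the upper 25% of domains by corner score (3.33%) nor at 20 kb tolerance (20.8%). Anchors near a domain end passed the threshold when each was placed on its own inside domains (30.2% against 22.3%, p = 0.0106, n = 202) and at 2 kb (21.3%), and lay under the shifted value at 10 kb (36.1% against 40.7%, p = 0.239) and 20 kb (44.1%). The first of these placed no anchor in the gaps between domains, where 35 of the observed anchors lay, so it is not a like comparison. The median domain length rose to 31 kb in the upper 50% and 38 kb in the upper 25% by corner score, the score itself rising with length. The correlation of corner score and length fell to 0.28 and 0.15 there. In these subsets X minus the autosome arms changed sign, to -1.5 kb (permutation p = 0.685) and -4 kb (p = 0.571), the cause not being tested. The difference between arms was not past the threshold in the upper 25% (H = 5.99). Fewer domains were tested there, so lower power could not be told apart from a smaller difference. The difference between arms remained past the threshold without chromosome 4 (H = 12.1, permutation p = 0.0171) and with blocks of 20 neighbouring domains permuted (p = 0.00855). Loop numbers per arm passed it with expected values by number of domains (chi-square 11.8, p = 0.0399). The number of distinct anchors ranged from 192 to 202. Alternatives with loops under 1 Mb, with linked loops counted once and with loop numbers on the 5 large arms were chosen after seeing the data. The alternatives set out for gene lists and sequence were not run. Depth could not be assessed.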

Other observations

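The tests of trios of anchors, of the anchors of loops over 1 Mb, of the grid of domain ends, of the arm ends and of anchors at 5 to 20 kb from domain ends were chosen after the results had been seen, and so were the share of loop pairs closed among the trios and the criterion of the grid test.

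On most large arms, domains covered less of the end at the centromere than of the other end, by little on X, and coverage was not tested per arm. In the 2 Mb at the centromere end, domains covered 53.5% of 2L, 45.8% of 2R, 46.2% of 3L and 71.2% of X, against 83.0, 75.8, 65.4 and 76.8% in the 2 Mb at the other end, while 3R went the other way (81.4 against 72.4%). Stretches over 50 kb between domains made up 2.7 Mb of these 5 centromere ends, against 0.797 Mb after circular shifts (central 95% from 0.211 to 1.77 Mb, n = 92 stretches, p = 0.0002, the smallest the shifts can give). They came to 1012 kb on 3L, 859 kb on 2L, 498 kb on X, 331 kb on 2R and none on 3R, not counting sequence outside the first and last domain of an arm. Loop anchors were found there too, 2 to 4 per arm. Repeats that keep reads from being placed would give the same picture, and this could not be tested without the sequence.

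Loops over 1 Mb shared anchors with shorter loops. Of their 13 distinct anchors, 3 overlapped an anchor of a shorter loop, on 2R at 10895001 to 10905001 and 10990001 to 11000001 and on X at 900001 to 908001. Random placement with the same widths gave 0.263 (central 95% from 0 to 2, n = 13, p = 0.003), but it ignores that both 2R anchors belong to loops with a shared anchor. With such linked anchors counted once, 2 of 6 sets overlapped, against 0.259 (central 95% from 0 to 1), and 2.2% of 10000 random placements reached 2. Chance overlap is thus disfavoured only narrowly, by 2 loci and in tests chosen after the overlap was seen.

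Among loops under 1 Mb, 10 trios of anchors were joined by 3 loops, and 4 of the 10 came from the 4 anchors on 3R. Draws of as many loops from the anchor pairs up to 240 kb apart gave 18.4 trios (central 95% from 11 to 27, n = 113, p = 0.034), more than observed. The share of meeting loop pairs closed by a further loop, computed after that number had come out low, went the other way, with 73.2% (30 of 41) against 44.2% in the draws (central 95% from 31.3 to 56.0%, n = 113, p = 0.0002, the smallest the draws can give), and was 62.1% without the 3R set, for which no draws were made. The draws can leave an anchor without a loop, which the list cannot, so they are not a clean comparison for either value, and whether loops close into trios more often than by chance remains open.

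Anchors were over-represented right at domain ends and under-represented a little further in. Domains with both ends on a 5 kb grid do not account for the first part. Without them 19.8% of anchors were within 2 kb against 11.9% after shifts (central 95% from 7.43 to 16.8%, n = 202, p = 0.0024). The 505 domains with both ends on a 2 kb grid but not on the 5 kb one stayed in, so coarse ends in general were not tested. Long domains around loops may not account for all of the second part. Moved at random inside their own domains, 28.4% of the 167 anchors lay at 5 to 20 kb from the ends, against 15% observed. The central 95% ran from 22.2 to 34.7% (n = 167, p = 0.0002 by random moves, the smallest these moves can give). That band was chosen after anchors had been found to be few there, so this p can be too small. The whole share within 20 kb, which also holds the excess at the ends, was 35.9% against 41.7%. It lay at the lower edge of the central 95% (35.9 to 47.9%, n = 167, p = 0.0646 by random moves), which does not exclude long domains. In 18 loops both anchors lay within 5 kb of a domain end, against 10.5 when anchors were re-paired within the arm (central 95% from 7 to 15) and 9.99 after circular shifts (n = 120, p = 0.0366). By definition these 18 include the 12 loops at a domain corner within 5 kb, so this excess is not separate from the corner result. A candidate explanation is that the list mixes loops at domain corners with loops deep inside domains, but a domain caller that reads a loop as a corner remains open, since both lists come from 1 map, and no biological explanation was tested.

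Domains around loops were long and scored high. The median domain around an anchor was 136 kb long, above the 94.2 kb that circular shifts gave (central 95% from 66 to 132 kb, n = 167, p = 0.0318), so the larger target of long domains does not account for all of it. A loop fits only in a longer domain, and placing the 77 inside loops at random in such domains gave an even longer median, 209 kb (central 95% from 175 to 250 kb), against 150 kb observed, so this selection remains open as the reason. The 58 domains with a whole loop had a mean corner score of 1.56 ± 0.23 (SD) against 1.29 ± 0.29 for the other 2068. The difference was 0.273. Permuting labels inside classes of domain length gave 0.185 (central 95% from 0.122 to 0.246, n = 58, permutation p = 0.0038). The class of the longest domains reached 740 kb, and the domains with a whole loop had a median length of 150 kb. Lengths inside that class could still differ widely, so whether length alone explains the score remains open. Read depth, an effect of a loop on the score of its domain, and biological explanations were not tested.

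The share of domains with both ends on a 5 kb grid changed with length. Both ends lay on a 5 kb grid in 33.6% of the 405 domains of 60 kb or more (exact interval 29.0 to 38.4%) and in 2.44% of the 1721 shorter ones (1.76 to 3.28%). Ends spread evenly over the 500 bp grid would put 1% there, below both intervals, so the ends were not placed evenly. Calls merged from several bin sizes may account for this but were not tested: a first criterion left them undecided, because the shorter domains also exceeded 1%, and the one set after it, that long domains exceed short ones, only restates the pattern.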
